A study of Mus musculus with 2 samples.

How the data were processed

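RNA sequencing was done on fibro/adipogenic progenitors (FAPs), the mesenchymal stromal cells of skeletal muscle, sorted from C57BL/6 mice and grown in medium with 20% fetal bovine serum. Per the labels' protocols, the cultures received 1 µM recombinant mouse Musclin, a peptide secreted by muscle, or its vehicle for 72 hours, with the medium changed every day. There was 1 library per group. The spread between replicates could therefore not be measured, and no test across samples was run.

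The values came from the authors' deposited table of 179 genes, each marked as significant. It holds the authors' fold change and its log2 value, a p-value, an adjusted p-value and an expression level for each library. Per the file header, the fold change is the Musclin library over a library headed PBS. PBS was taken as the vehicle, because it is the other library of the table and the denominator, although the labels do not name the vehicle. The level columns are printed a second time with identical values for all 179 genes, and were used once. RSEM, edgeR and GRCm38.p5 are named in the submitters' processing notes, without versions or roles. The aligner, the annotation release, the filter on low values, the scaling, the dispersion used without replicates and the strandedness of the libraries are not given in the sources used here. The unit of the deposited expression signal is not stated in the file header either. RSEM gives TPM and FPKM, and these values cannot tell which one is meant, so they are called levels here. They depend on estimated transcript lengths and on how reads that fit several genes were divided. The fold of the authors' deposited table is finite for genes at a level of 0 in 1 library, so an offset was added before the ratio was taken. No fold is quoted for those genes. Read counts and library totals were not available for this work, so the depth is unknown and no counting interval or detection limit was computed.

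The number of genes the authors tested was worked out from the p-values of the authors' deposited table. Under the Benjamini-Hochberg adjustment, the number tested times p over adjusted p is a gene's rank by p, if the adjusted values are left as computed. They were, since 8 listed genes have a smaller adjusted p than the listed gene before them in order of p. With 23180 tests this rank was whole, within 0.001, for all 178 genes with a p above 0. On simulated data with known numbers of tests, the procedure recovered the number in 10 of 10 simulations, each with 170 genes. Unlike the authors' values, the simulated adjusted p were not allowed to fall as p rose, so the simulated setting differed in this. The authors' p-values compare these 2 libraries, not the conditions, and were only copied and counted.

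Gene type and position were taken from GENCODE M21, an annotation of GRCm38, for 178 of the 179 gene IDs. BLAST+ 2.17.0 (megablast) was used to align the longest transcript of each listed gene with all M21 transcripts. A gene was said to have a near-identical copy when another, non-overlapping gene matched at 95% identity or more over at least 50% of the transcript. Sequence identities given below, also where sequences are called identical, are those of the aligned part. The share was set beside 1000 random sets of annotated genes of the same types. All transcripts of the listed genes were also searched for annotated ribosomal RNA (360 transcripts, none of them named 28S; 80% identity over 50 nt or more). Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

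The groups, 30 gene lists (1010 distinct genes), the rule for named genes and the alternative settings were fixed before the data were examined. Of the genes with a level of 1 or more in the higher library, the rule named up to 12 of the largest rises and up to 12 of the largest falls among genes with an ordinary symbol, not a Gm number, Rik clone, pseudogene or bare ID. It gave 12 rises and 11 falls, since no further fall qualified. It also named up to 4 listed members of each gene list, and Ostn, Npr1, Npr2, Npr3 and Filip1l where listed. Filip1l was put into the rule and into the list of musclin and natriuretic peptide signalling from prior knowledge of published work on Musclin, not from the labels, so its place there is not independent of the study. This gave 31 genes, and any other gene named was chosen after its values were seen. The alternatives were adjusted p thresholds of 0.01 and 0.001, a log2 fold of 2, the level minimum of 1, leaving out provisional gene names, and ratios of the levels with no pseudocount or with pseudocounts of 0.1 and 5. A p-value adjusted over the list alone needs the unlisted members, which were not analysed here. No enrichment test was run, because its background would be all genes tested.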

Results

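The transcriptome of FAPs was compared between 1 culture treated with Musclin and 1 culture treated with vehicle, to ask which genes change after 72 hours of exposure. Musclin (osteocrin, encoded by Ostn) is a secreted muscle peptide that binds the natriuretic peptide clearance receptor Npr3. The authors' deposited table held 179 genes, of which 116 were higher and 63 lower in the Musclin library. Protein-coding genes made up 59 of those higher and 26 of those lower. The remainder comprised 25 processed pseudogenes, 50 noncoding RNAs, 17 loci whose type the annotation leaves to be established, Mx2, which is annotated as a polymorphic pseudogene, and 1 gene ID without an annotation. Folds in the authors' deposited table were at least 2.006 for higher genes and at most 0.477 for lower genes, and the largest adjusted p was 0.0497. These genes were 0.772% of the 23180 genes tested. By p, the highest rank among them was 1222, so 1043 further genes had a p no larger than that of the last listed gene and were not analysed here. A gene that is not listed is therefore not shown to be unchanged. Every fold below compares 1 library with 1 library and has no replicate check, and the depth of the libraries is unknown.

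**Figure D1:**
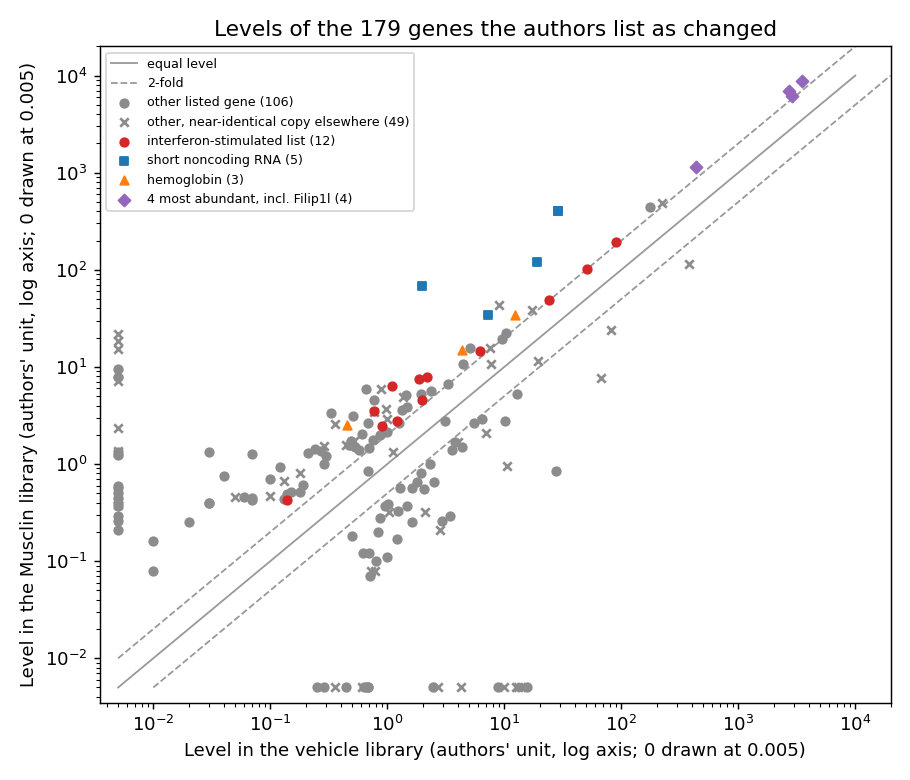
Expression levels of the 179 listed genes in the vehicle library (x axis) and the Musclin library (y axis), both in the authors' unstated unit on log axes, 1 point per gene and 1 library per group, with a solid line at equal levels, dashed lines at a 2-fold difference, gene groups in colour and genes at 0 drawn at 0.005. The 12 interferon-stimulated genes and the 5 short noncoding RNAs lie above the line of equal levels. The 4 genes with the highest levels, marked as most abundant, stand at the upper right.

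Interferon-stimulated genes formed the largest group of known function. Of the 65 genes in this list, 12 were higher in the Musclin library, 0 were lower and 53 were not listed. Cxcl10 (5:92346638-92348889, GRCm38, minus strand), a chemokine that attracts activated T cells, had a level of 1.09 with vehicle and 6.29 with Musclin, and a fold of 5.65 in the authors' deposited table (adjusted p = 1.3e-09). Mx1, a gene of the family of dynamin-like GTPases, had levels of 0.77 and 3.54, and Rsad2, the antiviral enzyme viperin, had 0.90 and 2.46. The adjusted p of Mx1 and Rsad2 in the authors' deposited table were 2.98e-09 and 4.91e-08. Tgtp2, an interferon-induced GTPase, went from 1.86 to 7.54, but its transcript is 99.8% identical to that of Tgtp1. The listed members with the highest levels had the smallest folds, a relation that the filter on fold and adjusted p can produce by itself. Ifit3 had a level of 91.0 with vehicle and 191.9 with Musclin, Ifit1 had 51.4 and 102.3, and Ifit3b had 24.1 and 48.6. Folds for Ifit3, Ifit1 and Ifit3b in the authors' deposited table were 2.12, 2.01 and 2.03. Ifit3 and Ifit3b are 97.8% identical, so their reads can be divided between them, although both were higher. Mx2, Cmpk2, Ddx60, Cxcl9 and Oas3 were the other members, with folds of 2.27, 2.32, 2.32, 2.50 and 3.68 in the authors' deposited table. A transcript of Ddx60 holds sequence that matches annotated ribosomal RNA. Hemoglobin transcripts, markers of red blood cells, were higher in the same library (Hbb-bs, levels of 12.3 and 33.9). None of the 24 genes of antigen presentation was listed.

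**Figure D2:**
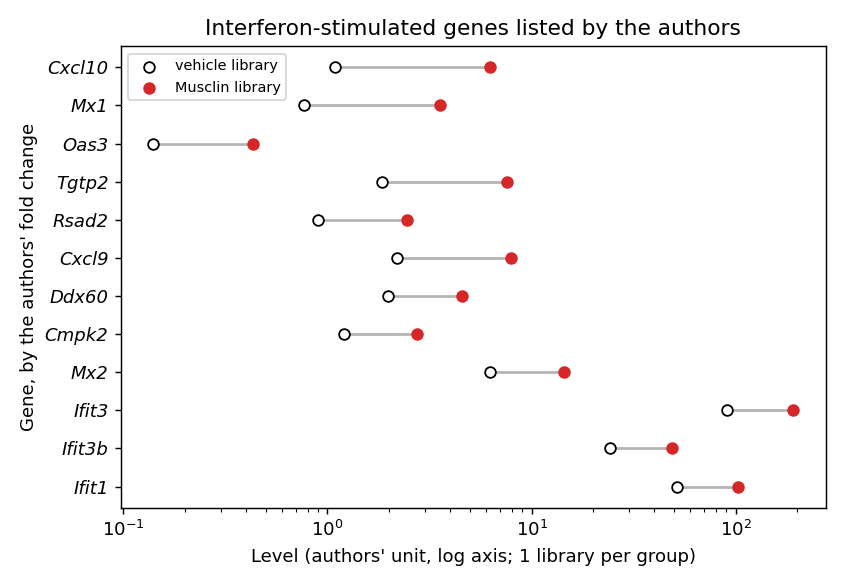
Levels of the 12 listed interferon-stimulated genes in the vehicle library (open circles) and the Musclin library (red circles), in the authors' unstated unit on a log axis, ordered by the authors' fold change; 1 library per group, so there are no error bars. All 12 are higher with Musclin, from Ifit1 (2.01-fold) to Cxcl10 (5.65-fold).

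Filip1l, which encodes a filamin A interacting protein and spans 16:57353093-57573126 (GRCm38, plus strand), was among the listed genes with the highest levels. Its level was 2890 with vehicle and 6134 with Musclin, a fold of 2.07 in the authors' deposited table, where its p is printed as 0. It lies inside Cmss1, which is annotated on the opposite strand. Overlap was judged on whole gene spans, introns included, and exons were not compared. Since the strandedness of the libraries is not given, reads of the 2 genes may not be told apart wherever their exons overlap. The ratio of the levels was 2.12. The other genes of high level named here were chosen after their values were seen. The noncoding RNA Gm26561 had levels of 3520 and 8695, Tmtc2 had 2709 and 6888, and the noncoding RNA D130009I18Rik had 433 and 1145. The folds of these genes in the authors' deposited table were 2.35, 2.21 and 2.57. Together with Filip1l they held 85.9% of the summed level of all listed genes with vehicle and 88.4% with Musclin. The next listed gene by vehicle level, the processed pseudogene Rpl27-ps3, was lower, with levels of 380 and 114. In the authors' deposited table, Ifit1 had a smaller fold than Gm26561, Tmtc2 and D130009I18Rik, a vehicle level of only 51.4, and yet a smaller p. The high levels of Gm26561, Tmtc2 and D130009I18Rik therefore need not mean many reads. Abundance here means level only. Of the 17 genes of musclin and natriuretic peptide signalling, Filip1l, which was put there from prior knowledge of work on Musclin, was the only one listed. Ostn, Npr1, Npr2 and Npr3 were not listed.

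Among the listed genes were 5 short structural RNAs, all higher in the Musclin library, which were grouped after their values were seen and belong to none of the gene lists. Rmrp, the RNA of the RNase MRP complex, had a level of 1.99 with vehicle and 68.6 with Musclin, a fold of 33.0 in the authors' deposited table (adjusted p = 9.49e-07). Rn7s1 and Rn7s2, copies of the 7SL RNA of the signal recognition particle with identical sequence and identical printed values, had levels of 28.8 and 401.4 and a fold of 13.5 in the authors' deposited table. Rn7sk, the 7SK RNA that restrains transcription elongation, went from 19.2 to 120.1, a fold of 6.13 in the authors' deposited table. Its aligned part is identical to Gm24447. Rpph1, the RNA of RNase P, was outside the naming rule and had levels of 7.28 and 34.0. All 5 are 271 to 331 nt long. Of the 26 members of the list of mitochondrial genome and biogenesis, which also holds nuclear genes, only mt-Co3 was listed. This gene, which encodes a subunit of cytochrome c oxidase, had levels of 225 and 489. The aligned part of its transcript is identical to Gm28437.

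Hemoglobin genes were the listed members of the lymphoid, mast and erythroid list, with 3 of 25 higher and 0 lower. Hbb-bs had a level of 12.3 with vehicle and 33.9 with Musclin, Hba-a1 had 4.39 and 14.9, and Hbb-bt had 0.45 and 2.53. Their folds in the authors' deposited table were 2.75, 3.67 and 5.59. Hba-a1 is 99.8% identical to Hba-a2, which was not listed. Of the marker lists for other cell types, those of macrophage and myeloid cells, endothelial cells, myogenic cells and Schwann and neural cells had 0 listed members. The list of tendon, cartilage and bone cells had 1 of 32, Ibsp, a bone matrix protein, at levels of 0.29 and 0.99.

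Of the list of chemokines and inflammatory cytokines, which leaves Cxcl9 and Cxcl10 to the interferon-stimulated genes, 1 of 51 was higher and 1 was lower. Ccl5, which attracts T cells and monocytes, had a level of 0.77 with vehicle and 4.53 with Musclin, a fold of 5.90 in the authors' deposited table (adjusted p = 0.0266). Ccl19, a ligand of Ccr7, was lower, with levels of 2.84 and 0.21 and a fold of 0.074 in the authors' deposited table (adjusted p = 0.00711), and it is 98.9% identical to Gm2564. The other 49 genes of this list were not listed. C7, a component of the membrane attack complex, was the 1 listed member of 22 complement genes and was lower, with levels of 1.02 and 0.39.

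Further genes with large rises included Slc17a9, a vesicular nucleotide transporter, with levels of 0.03 and 1.33. Pdzk1, a scaffold protein, had 0.66 and 5.97, and Kcnk4, a potassium channel, had 0.47 and 1.56. Folds for Slc17a9, Pdzk1 and Kcnk4 in the authors' deposited table were 15.3, 6.11 and 5.57, whereas the ratios of the levels were 44.3, 9.05 and 3.32. Gm26561, Tmtc2, D130009I18Rik, Pdzk1, Agbl1, Alkal2, Aspg, Rmrp, Tgtp2, Cxcl10, Ccl19 and C7 also overlap the span of a gene on the opposite strand. The limit given for Filip1l holds for them, again only wherever exons overlap, which was not checked. Agbl1 and Mup10 were listed at 0 with vehicle and at 7.92 and 1.29 with Musclin, and Mup10 is 98.5% identical to Mup18. Among the named genes above 0 in both libraries, the largest fall in level was in Entpd1 (19:40612366-40741602, plus strand), which encodes the ATP-hydrolysing ectoenzyme CD39. Its level was 27.6 with vehicle and 0.85 with Musclin, a level ratio of 0.0308, whereas the authors' deposited table gives a fold of 0.31 (adjusted p = 3.24e-09). Nek3, a kinase of the NIMA family, had levels of 3.55 and 1.41, and Bvht, a long noncoding RNA, had 12.9 and 5.29. Hoxa13, a transcription factor of limb patterning, had 1.23 and 0.33. Aspg, Alkal2, Pcdhb7 and Nhej1 were also lower, with folds between 0.358 and 0.45 in the authors' deposited table. Histone genes gave 1 higher and 1 lower of 53. Hist1h2bq was at 4.27 with vehicle and listed at 0 with Musclin, while Hist1h2br, which is 99.8% identical to it, had levels of 0.98 and 3.67, a level ratio of 3.74 against a fold of 2.41 in the authors' deposited table.

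Among the 30 gene lists, 22 had no listed member. For the cells themselves, these were FAP identity (24 genes), adipogenesis and lipid storage (34), extracellular matrix and fibrosis (57), matrix proteases (23), and contractile and smooth muscle genes (25). For growth and death, they were cell cycle and proliferation (79), apoptosis (55), p53 targets (26), and growth and trophic factors (48). The signalling lists were TGF-beta and BMP response (27), Wnt, Notch and Hedgehog (41) and immediate early genes (33). The metabolic and stress lists were ER stress and amino acid response (36), cholesterol biosynthesis (23), glycolysis and hypoxia (32), and oxidative stress and metallothioneins (28). The others were antigen presentation (24), long noncoding RNAs and dosage genes (15), and the markers of macrophage and myeloid (36), endothelial (20), myogenic (45) and Schwann and neural cells (17). For these genes the table shows only that they did not meet both criteria of fold and adjusted p, or were not among the genes analysed here. The share of all listed genes that were higher was 64.8%.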

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

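With 1 library per group, no replicate could be left out, and no replicates could be matched. No paired analysis was possible because a single pair of libraries leaves no spread to estimate. Depth is unknown, so no counting limit could be set. Genes at low levels carry the least evidence: 54 of the 179 listed genes were under a level of 1 in both libraries, and 41 were at 0 in 1 of them. An adjusted p of 0.01 or less kept 106 genes (72 higher, 34 lower), and 0.001 or less kept 68 (52 higher, 16 lower). An absolute log2 fold of 2 or more kept 97 genes (61 higher, 36 lower), 5 of the 23 listed members of gene lists, and 1 of the 12 interferon-stimulated genes, Cxcl10. Leaving out Gm numbers, Rik clones, pseudogenes and bare IDs kept 68 genes (53 higher, 15 lower). The next 3 alternatives were chosen after seeing the data. Leaving out genes with near-identical copies kept 123 genes, 15 of the 23 members of gene lists and 9 of the 12 interferon-stimulated genes. Leaving out genes at 0 kept 138 genes, and requiring the ratio of levels to be 2-fold in the same direction kept 173. None of the named genes reversed under the level ratios, but Entpd1, Slc17a9, Kcnk4 and Hist1h2br (4 of the 28 above 0 in both libraries) moved by over 1.5-fold without a pseudocount. With a pseudocount of 5, 10 of the 31 named genes had a log2 ratio of 1 or more in size, compared with 31 at 0.1, a loss that follows from low levels. The named interferon-stimulated genes Cxcl10, Tgtp2, Mx1 and Rsad2 were all below 1 at this setting (0.89, 0.87, 0.57 and 0.34). Ifit1, Ifit3 and Ifit3b, with higher levels, were not among the named genes.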

Other observations

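The tests given here were chosen after the results were seen, except that of transcript length. Interferon-inducible genes outside the fixed list were also higher in the Musclin library. Ifi47, an interferon-induced GTPase that overlaps Gm12188 on the opposite strand, had levels of 10.4 with vehicle and 22.6 with Musclin, Gbp9, a guanylate-binding protein, had 3.31 and 6.73, and Ifi208, which is 96.4% identical to Ifi213, had 0.10 and 0.47. They were chosen after their values were seen. Gm3892 was the 1 gene of the 138 above 0 in both libraries whose levels (1.12 and 1.33) went against its listed direction (a fold of 0.411 in the authors' deposited table). For 8 of these 138 genes, the fold in the authors' deposited table and the ratio of the levels differed by over 1 on the log2 scale, among them Entpd1.

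The first pattern is the rise of 12 interferon-stimulated genes. A single wrong scaling factor would move all genes alike and give those with as many reads as Ifit1 (2.01-fold in the authors' deposited table) about as small a p, yet Ifit1 ranked 9 by p, so 0.0388% of all genes tested had a p that small. This argues against such a factor as the whole cause if at least 1% of the genes have as many reads, which was taken as given and not measured here. Earlier forms of the test, also written after the values were seen, used the share of tested genes that are listed (0.772%). Next came the share up to the highest rank (5.27%), which left the question open, so the support is weak. Red blood cells carried over into the Musclin library, although the cells were sorted (the gate is not given in the sources used here), are a candidate source because 3 hemoglobin genes, the main transcripts of such cells, rose by 34.1 in summed level, which was 0.193 times the summed rise of Ifit1, Ifit3 and Ifit3b (176.3) and argues against red cells for these genes, but was 1.02 times that of the other 9 members (33.6), for which they stay open. An effect of Musclin and a difference between 2 cultures that Musclin did not cause cannot be told apart, since there was 1 library per group.

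The second pattern is the rise of 5 short noncoding RNAs (4.55-fold to 33.0-fold in the authors' deposited table). It also takes in the 4 listed genes with the highest levels, Filip1l included (2.07-fold to 2.57-fold there). These 4 genes were grouped after their values were seen. By vehicle level, Rpl27-ps3 came next and was lower (380 and 114), and mt-Co3 and Camk1d followed and were higher. More short RNA kept in the Musclin library may account for the noncoding RNAs: of the 9 other listed genes with a longest transcript under 400 nt, 44.4% were higher, against 65.2% of the 164 longer ones. This difference of -20.8 percentage points (standard error 17.0) lies below the bound of 10 set beforehand, which by itself argues against that explanation, but 7 of the 9 genes have a near-identical copy elsewhere and 8 are at 0 in 1 library. Their annotated length therefore need not be that of the RNA sequenced, a limit seen only after the test, and the explanation stays open. Also open are ribosomal RNA sequence at the 4 abundant genes (0 of 4 matched annotated ribosomal RNA, but 28S sequence and introns were not searched), more RNA without a poly(A) tail (0 listed histone genes lacked a near-identical listed copy), and an effect of Musclin, which was not tested.

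The third pattern concerns which genes were listed, since near-identical copies elsewhere were found for 56 of 178 listed genes (31.5%), against 5.6% to 19.1% in 1000 random sets of the same gene types. The share was 45.0% among the 40 annotated genes at 0 in 1 library and 27.5% among the other 138. Of 18 pairs of listed genes that are copies of one another, 11 were listed in opposite directions, such as Hist1h2bq and Hist1h2br or Gm14308 and Gm14434. No expected count of opposite pairs was computed, and several pairs share genes, such as those among Gm10095, Gm10163, Gm10240 and Rpl21-ps15. The pair of Gm10593 and Gm3892 counts as opposite although the levels of both rose. The pair count therefore decides nothing by itself. As a hypothesis, reads shared between copies may have been divided differently in the 2 libraries, as the high share of genes with copies would allow. The random sets were not matched on expression, however, and real changes of single copies were not tested.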
